A study of Gallus gallus with 6 samples.

How the data were processed

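The samples were cranial microdissections of chick embryos. Per the labels' protocols, embryos were electroporated and dissected, nuclei were cross-linked and sonicated, biotin-tagged chromatin was captured on streptavidin beads, and libraries were sequenced on a NextSeq 500. The same protocol text is attached to the PAX7 CUT&RUN samples, and it describes the biotin ChIP rather than CUT&RUN, so the steps specific to CUT&RUN are not given in the sources used here. Per the submitters' processing notes, Bowtie, Subread 1.4.5, featureCounts, MACS2 and HOMER 4.7 were used and the build was galGal6; the notes used here give no role, order or parameters.

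Each deposited list has one row per summit with a sequence name, a 1 bp position, a peak name and a score. The score is a −log10 p- or q-value deposited by the authors; which of them it is, the cut-off and the control library are not given in the sources used here. Scores of lists that differ in depth are not on a common scale. They were therefore compared in size only within a list, and between lists only by rank, by correlation or side by side. Peaks were called per sample: each list has its own numbering, which runs without end gaps to 8638 and 28177. The unplaced sequences carried NT accessions in 773 and 757 names and NW accessions in 0, the naming of the galGal5 release rather than that of galGal6 as far as is known. The positions are therefore printed as the lists give them and the build is left open. The only gene table at hand is of the GRCg7b assembly, so none of its coordinates were used. Comparisons planned before the data were examined that need the lists' own genome were not run: the share near transcription start sites, genomic classes, gene lists, the CHD7 locus, motifs, and the filter on repeats.

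Replicates 1 and 2 of the PAX7 group were used, as the labels number them. Nothing in the labels says whether they came from separate pools of embryos. The lists do not hold identical values, but without read counts it could not be tested whether they share library material. Autosomes 1 to 33 with Z and W formed the assembled set; 1084 and 957 summits on unplaced sequences (an unplaced linkage group included) and 3 and 3 mitochondrial summits were kept out of the main comparisons. Chromosome spans were taken as the last summit of either list, since no sequence lengths were at hand. A summit was called shared when the other list had one within 250 bp. Chance sharing was estimated from 1000 seeded shuffles within chromosomes. Differences in median score were tested with 100000 permutations, shares with Fisher's exact test and Benjamini-Hochberg adjustment over 4 shares, and intervals were exact Clopper-Pearson at 95%. The positions named are the 10 with the highest mean percentile of score over both lists, a rule fixed before the data were examined; the windows, the chromosome shares and the clustering were chosen after seeing the data.

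Simulated lists of the same sizes were used to test the overlap count: with 0, 500 and 4000 planted shared summits, the excess over the shuffles was 9, 500 and 3951. Alternatives were distances of 100 and 500 bp, summits at or above the median score, equal numbers of top-scoring summits, the top 1% left out, all sequences, and replicate 2 moved by 10 kb. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.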

Results

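Binding of the transcription factor PAX7 in the cranial neural crest of chick embryos was mapped as lists of peak summits, the single base at which each called peak was highest. PAX7 is a paired-box and homeodomain protein of the neural plate border and neural crest, the migratory embryonic population that gives rise to craniofacial skeleton, peripheral neurons, glia and pigment cells. The study's title names the chromatin remodeller CHD7 as the gene whose regulation by tissue-specific factors was examined, and its design pairs PAX7 CUT&RUN, in which an antibody-tethered nuclease releases bound DNA, with biotin ChIP-seq for SOX10, a neural crest factor of the SOX family. Of the 6 samples in the series, 3 were PAX7 CUT&RUN, 2 were SOX10 ChIP and 1 was the ChIP input. Summit lists of 2 PAX7 samples, replicates 1 and 2, were analysed; the third PAX7 sample and the SOX10 and input samples were not analysed here. The labels give both samples as wild-type cranial microdissections and state no developmental stage, but the peak names begin with HH12 in replicate 1 and with HH9 in replicate 2, the abbreviation used for Hamburger and Hamilton stages. A difference between the replicates and a difference between stages could therefore not be separated, and no statement below assigns either sample to a stage.

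The list of replicate 1 held 8638 summits and that of replicate 2 held 28177, 3.26 times as many. On the assembled chromosomes, which the comparisons below use, there were 7551 and 27217 summits, a median of 71.2 kb and 22.6 kb apart. The peak caller's score, the −log10 of its p- or q-value, had a median of 6.21 in replicate 1 and 6.70 in replicate 2, with minima of 2.05 and 2.02. The lists carry no read counts, so the sequencing depth behind them is unknown. Intervals and p-values below are over summits, which are not replicates: they cover counting error in these 2 libraries only.

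The first comparison asked how far summit positions recurred between the samples. The control library is not given and the filter on repeats was not run. Recurrence of summits therefore does not by itself show that PAX7 was bound there. Most positions of the shorter list recurred: 6452 replicate 1 summits, 85.4% (95% exact binomial interval 84.6 to 86.2%), had a replicate 2 summit within 250 bp. The reverse share was 23.5% (23.0 to 24.0%), or 6404 replicate 2 summits. When replicate 2 summits were shuffled within their chromosomes, 104 ± 10.3 replicate 1 summits were shared (SD over 1000 shuffles), so that the observed number was 62.1-fold higher (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). Moving replicate 2 by 10 kb, which keeps its local density, left 126 shared summits. Shared summits lay a median of 37 bp apart (interquartile range 17 to 72 bp), and 66 were at the same base. With equal numbers of top-scoring summits from each list, 4238 of 7551 replicate 1 summits were shared, 56.1% (55.0 to 57.2%), and 4151 of 7551 replicate 2 summits, 55.0% (53.8 to 56.1%).

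Shared positions had higher scores than unshared ones in both samples. In replicate 1 the median score was 6.20 for shared and 5.13 for unshared summits, a difference of 1.06. Without the top 1% of scores of each list it was 0.53. Sharing was called anew in these trimmed lists, so that unshared replicate 1 summits rose from 1099 to 1316 and their median to 5.53. The smaller value therefore does not show that the difference rests on extreme scores. In replicate 2 the medians were 11.3 and 6.11, a difference of 5.21. Both differences had p = 1e-05, the smallest that 100000 permutations can give (two-sided permutation test of medians). In replicate 2 the shared percentage rose at every decile of score, from 4.45% (3.70 to 5.29%) in the lowest to 79.1% (77.5 to 80.6%) in the highest. In replicate 1 it was 76.6% (73.4 to 79.6%) in the lowest decile and 92.5% (90.3 to 94.2%) in the highest. Over the 6452 shared summits, the 2 scores were related with Pearson's r = 0.49 on the log10 scale and Spearman's rho = 0.47 (each permutation p = 1e-05; r = 0.49 without the 2 summits farthest from the median). This relation is across positions, which are not independent replicates, and it was the only one computed. Of the 100 highest-scoring replicate 1 summits, 32, or 32.0% (23.0 to 42.1%), had a partner among the 100 highest-scoring of replicate 2. Partners of lower score are left out of this count. With longer lists of equal length it was 46.2% of 1000 and 56.1% of 7551.

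**Figure D1:**
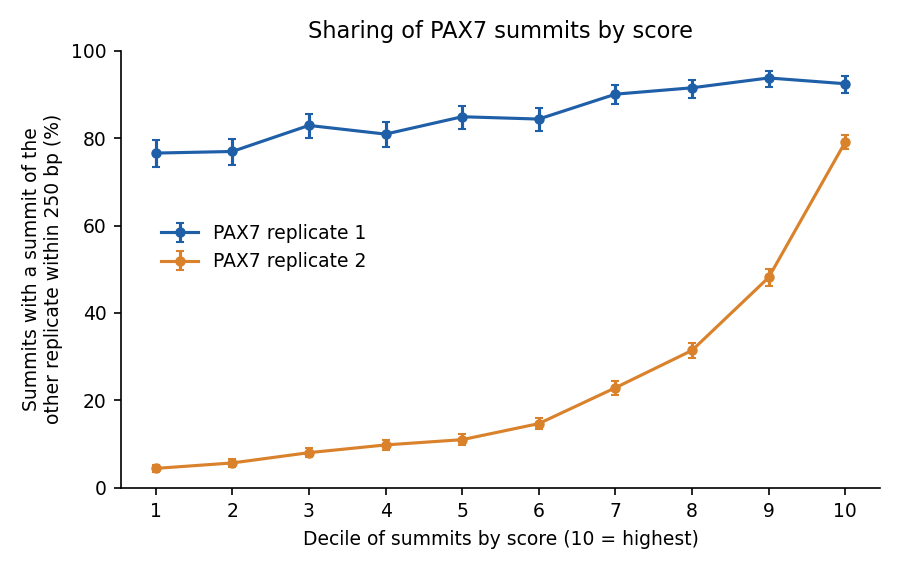
Percentage of summits with a summit of the other replicate within 250 bp (vertical axis) in each decile of the list ordered by peak-caller score (horizontal axis), for PAX7 replicate 1 (blue) and replicate 2 (orange); bars are 95% exact binomial intervals. Replicate 2 rises from 4.45% to 79.1%, whereas replicate 1 begins at 76.6%.

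The highest-scoring shared position was a site on chromosome 2 that led both lists. The 10 shared positions with the highest mean percentile of score lay on chromosomes 1, 2, 4, 5 and 7. Coordinates are 1-based, as the lists give them; the submitters' processing notes name galGal6, whereas the sequence names in the lists follow another convention, so the build is left open. The leading site on chromosome 2 was at 49766781 in replicate 1 (score 212) and 49766760 in replicate 2 (score 267). A pair on chromosome 4 came next, at 22427029 and 22424254 in replicate 1, 2775 bp apart, with scores of 97.1 and 83.0. The replicate 2 summits of this pair, at 22427022 and 22424255, scored 99.7 and 88.8. On chromosome 1 the positions 172697216 and 12797054 scored 29.1 and 26.5 in replicate 1, and their partners 42.5 and 48.6 in replicate 2. The position 140282560 on chromosome 2 scored 99.4 in replicate 1 and 27.4 in replicate 2. The other 4 were at 42935662 on chromosome 5, at 21388821 and 10427698 on chromosome 2 and at 20963711 on chromosome 7, with replicate 1 scores of 26.2 to 27.2 and replicate 2 scores of 35.3 to 40.7. Genes, exons and the CHD7 locus were not assigned to these positions, because no annotation of the lists' build was used here. Whether any of them lies in a repeat was not tested either.

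In windows of 500 kb, the densest group of shared positions was on chromosome Z. It lay between 27000001 and 27500000, with 21 shared summits among 28 in replicate 1 and 29 in replicate 2. The 21 lay between 27142889 and 27314081, a median of 2.92 kb apart (0.48 to 62.0 kb). The same window was the densest of Z in each list taken alone. For the windows the shared positions themselves were shuffled, not the replicate 2 list. Placed evenly at random within their chromosomes, they never exceeded 17 in any window. The next densest windows held 13 each, both on chromosome 5, at 4500001 to 5000000 and at 11500001 to 12000000. Windows with 12 were found on chromosome 4 at 22000001 to 22500000, which holds the high-scoring pair described above, and on chromosome 6 at 20500001 to 21000000. When the windows were moved by 250 kb, the Z group was split and the densest windows held 13 shared summits, one of them on chromosome 1. With windows of 1 Mb the densest held 23 on Z, against 21 in the next. When these were moved the densest held 22, one of them on chromosome 6 and tied with another window. Sliding windows of 200 kb placed all 21 in one window on Z, against at most 9 on any other chromosome and at most 12 in the shuffles. Genome-wide, 17.1% of shared summits had another within 10 kb, against 12.8% after shuffling within chromosomes (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). With 1 replicate 1 summit kept per replicate 2 summit the percentages were 14.2 and 12.6 (permutation p = 0.004). With summits within 1 kb merged in the list and in each shuffle alike they were 11.4 and 11.6 (permutation p = 0.672). No excess within 10 kb was thus left after merging. Within 50 kb the percentages were 56.3 and 49.2 (permutation p = 0.001). Merging was not run at that distance, so an excess at longer range stays open.

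The last comparison was of the chromosomes themselves. Per Mb of the span covered by summits, the macrochromosomes 1 to 5 carried 8.66 summits in replicate 1 and 28.4 in replicate 2. Chromosomes 6 to 10 were close to this level, with 8.01 and 29.0 per Mb. The microchromosomes 11 to 33, pooled, were below it in both, at 4.88 and 21.6 per Mb, which is 0.66 ± 0.14 of the macrochromosome density (SD, n = 2). Chromosome 11 was an exception at 8.88 and 28.5 per Mb, and chromosome 12 carried 7.32 and 28.5. W was sparsest, with 8 and 18 summits. Among these classes Z differed most between the samples. It carried 3.00 summits per Mb in replicate 1 and 22.9 in replicate 2, 0.35 and 0.81 of the respective macrochromosome densities. Its density was 7.63 times as high in replicate 2 as in replicate 1, against 3.28 times on the macrochromosomes and 4.44 times on the microchromosomes as a class. Single microchromosomes with few summits reached a similar ratio, such as chromosome 18 with 31 and 244 summits (7.87 times). Chromosomes 17 and 24 stood at 7.36 and 7.42 times, and 19, 21, 23, 28 and 33 at 6.07 to 6.70 times. The ratio was 3.21 to 4.48 on chromosomes 11 to 15, and 2.90 to 5.86 on 16, 20, 22, 25, 26, 27 and 32. A high ratio was thus not particular to Z, and the pooled class does not show this.

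Expressed as a share of the summits on Z and autosomes, Z held 246 summits or 3.26% (2.87 to 3.69%) in replicate 1 and 1877 or 6.90% (6.60 to 7.21%) in replicate 2. The odds ratio was 0.45 (0.40 to 0.52; Fisher's exact test, two-sided, adjusted p = 2.62e-35 over 4 such shares). Of the Z summits, 90.7% of those in replicate 1 and 11.9% of those in replicate 2 were shared, against 85.3% and 24.4% on autosomes. The microchromosome share of autosomal summits was 11.8% in replicate 1 and 15.1% in replicate 2 (odds ratio 0.75, 0.69 to 0.82; Fisher's exact test, adjusted p = 1.09e-12). With equal numbers of top-scoring summits the microchromosome shares were 11.8% and 11.3% (odds ratio 1.05, Fisher's exact test, p = 0.402), so this difference did not hold there. Among summits at or above the median score of each list they were 10.4% and 12.6% (odds ratio 0.80, 0.71 to 0.90). Without the top 1% of scores the odds ratio was 0.75. The Z shares with equal numbers were 3.26% and 7.31%. W relative to autosomes gave an odds ratio of 1.54 (0.58 to 3.73; Fisher's exact test, adjusted p = 0.344), which these few summits could not tell from 1.

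**Figure D2:**
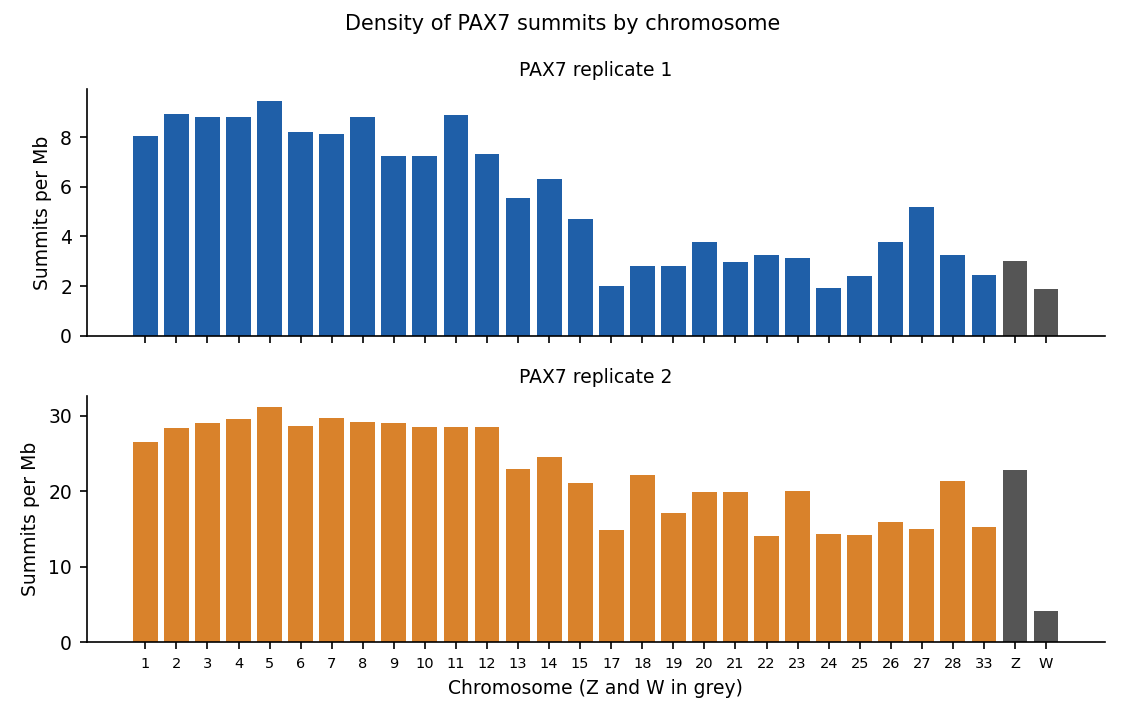
PAX7 summits per Mb (vertical axes, separate scales from 0) on each assembled chromosome with a span of at least 1 Mb, for replicate 1 (upper panel) and replicate 2 (lower panel), with Z and W in grey. Chromosome Z stands at 3.00 per Mb in replicate 1 and at 22.9 in replicate 2, while chromosome 1 stands at 8.04 and 26.5.

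**Figure D3:**
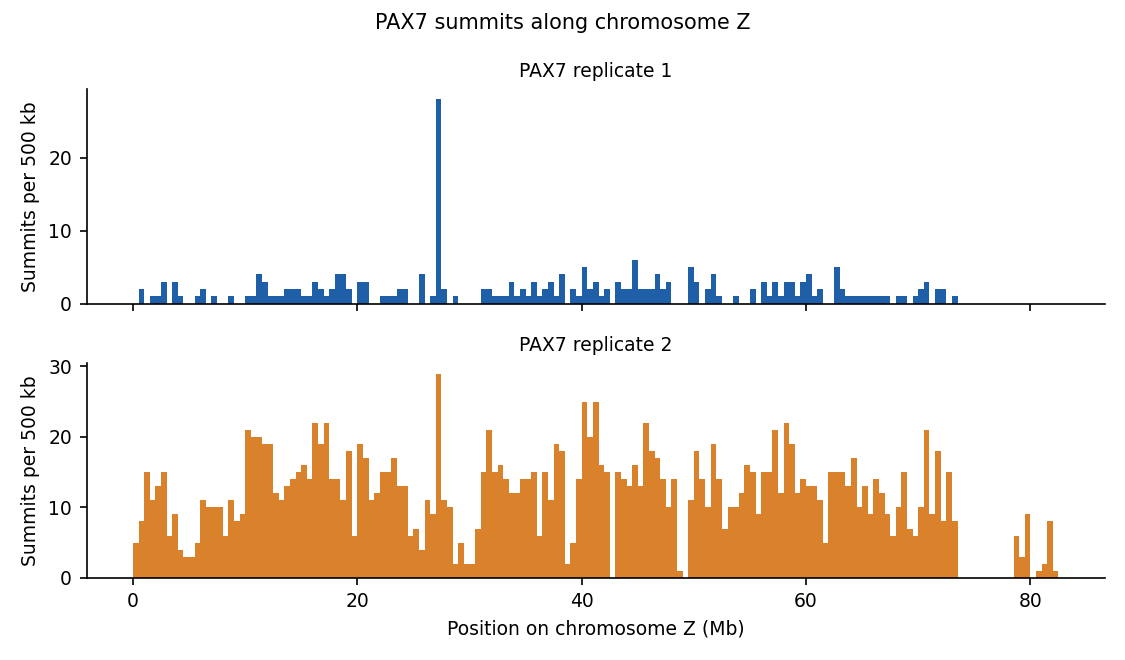
Number of PAX7 summits in each 500 kb window (vertical axes, separate scales from 0) along chromosome Z (horizontal axis, Mb) for replicate 1 (upper panel) and replicate 2 (lower panel). In replicate 1 the window from 27000001 to 27500000 holds 28 summits and the next densest 6. In replicate 2 the same window holds 29 and the next densest 25.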

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

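Summits on sequences outside the assembled chromosomes were part of neither the overlap nor the chromosome comparison. There were 1084 in replicate 1 and 957 in replicate 2, with no control list to set them against. They made up 12.6% of replicate 1 and 3.40% of replicate 2 (odds ratio 4.08, 3.73 to 4.47; Fisher's exact test, adjusted p = 1.14e-195 over 4 shares), the opposite direction to the chromosome Z share. Among summits at or above the median score the shares were 18.1% and 3.42% (odds ratio 6.25, 5.54 to 7.05). Their median score was 8.53 in replicate 1, against 6.04 on the assembled chromosomes, and 6.75 in replicate 2, against 6.70. Within 250 bp, 27.4% of those in replicate 1 and 30.0% of those in replicate 2 were shared, and 253 of the 774 and 758 sequences carried summits in both.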

How the results depend on the processing

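Of 59 alternatives to 14 results, 52 kept the direction and the side of the threshold, or stayed within the spread or within a set factor of the main count. This count includes the densities with one replicate left out, which lie within the SD of 2 values by construction and so test nothing. It also includes the 10 kb shift, which changes the chance background and leaves the count as it is. For the shared percentages, a value above the shuffles was enough to be counted as kept. The replicate 1 share was so counted at 56.1% with equal numbers of top-scoring summits. With all sequences it was 78.1%, against 85.4% in the main setting. Chromosome shares, clustering and windows, with their alternatives, were chosen after seeing the data. The number of shared summits was 3103 with summits at or above the median score and 4238 with equal numbers of top-scoring summits, both from shorter lists by construction, against 5535 to 6761 in the other alternatives, and it exceeded the shuffles in each. The share of replicate 2 summits that is shared rose from 23.5% to 55.0% with equal numbers of top-scoring summits, since the shared percentage rises with score. The score difference in replicate 1 fell from 1.06 to 0.53 without the top 1% of scores, where summits that lost their partner counted as unshared. The percentage of shared summits with another within 10 kb was 11.4% against 11.6% in the shuffles when summits within 1 kb were merged in both (permutation p = 0.672), and 14.2% against 12.6% with 1 replicate 1 summit per replicate 2 summit (permutation p = 0.004). The odds ratio of the microchromosome share turned from 0.75 to 1.05 with equal numbers of top-scoring summits; in replicate 2 the microchromosome percentage fell from 17.8% in the lowest decile of score to 8.86% in the highest, so it depends on how far down a list goes. The Z odds ratio stayed between 0.41 and 0.46 in every alternative run. The W density relative to macrochromosomes moved from 0.18 to 0.29 with summits at or above the median score; the cause was not tested. With one replicate left out, relative densities ranged from 0.35 to 0.81 for Z, 0.56 to 0.76 for microchromosomes, 0.93 to 1.02 for chromosomes 6 to 10 and 0.15 to 0.22 for W. The densest window held 13 shared summits when moved by 250 kb and 12 with 200 kb windows, which divide the Z group. Windows of 1 Mb gave 23 on Z and, when moved, 22 on chromosome 6, tied with another window. No paired analysis was possible because only one group has summit lists. No value could be had for the sharing results with one replicate left out. Without read counts, the lists cannot show how depth limits the number of summits called.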

Other observations

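The last replicate 1 summit on chromosome Z was at 73170542, and 32 replicate 2 summits lay beyond it, up to 82003341; no test of this is given, since the boundary is the last summit of replicate 1. Of the 21 shared summits in the dense Z group, replicate 1 scores ran from 3.72 to 12.3 and replicate 2 scores from 3.43 to 16.1, with 3 in the highest decile of replicate 1 and 1 in that of replicate 2. All tests in the next paragraphs were chosen after the result was seen, except that of the score ranks of Z summits between replicates; the comparison within replicate 1 that qualifies it was added later.

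Replicate 2 was 3.26 times as long and held most of replicate 1. A more sensitive library or call in replicate 2, with the same sites, may account for part of this on the autosomes. Its shared percentage rose with score, as that needs, but in the highest decile reached 79.1% over all assembled chromosomes and 81.3% over autosomes. Both values lie short of the 90% set as the mark for it and above the 50% that would have excluded it. The density ratio of replicate 2 to replicate 1 also differed between autosomes, at 3.28 on the pooled macrochromosomes and 7.87 on chromosome 18. Of the 100 highest-scoring replicate 1 summits, 32.0% had a partner among the 100 highest of replicate 2. Whether sensitivity alone gives these values was not tested. The HH12 and HH9 peak names leave a difference in stage equally open, and these cannot be told apart in one list of each.

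The lower Z share of replicate 1 is less easily put down to the length of its list. The same number of top-scoring replicate 2 summits held 7.31% on Z, above the replicate 1 share of 3.26% (2.87 to 3.69%), and in the highest decile of replicate 2 scores only 52.2% (45.1 to 59.2%) of Z summits were shared, against 81.3% (79.7 to 82.8%) of autosomal ones. These values argue against a stricter threshold or a loss of sensitivity equal for all chromosomes. A candidate explanation is fewer Z copies per cell in replicate 1, as a pool with more female (ZW) embryos would have. The prediction set beforehand was met: the rank of shared Z summits in replicate 1 minus that in replicate 2 was lower than for autosomal ones, by -9.80 percentile points (95% bootstrap interval -14.1 to -5.28, permutation p = 0.0001). It is not counted as support, since a summit is shared only if replicate 1 called it, so that any shortfall of Z there could give this value. Within replicate 1 the difference was -2.07 (-5.70 to 1.64). The W odds ratio, 1.54 (0.58 to 3.73), was undecided, and embryo sex, stage and Z-specific mappability stay open. Whether the similar density ratios of single small microchromosomes share a cause with Z was not tested.

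The group of 21 shared summits on Z went against the sparseness of that chromosome in replicate 1: the window held 11.4% of replicate 1 Z summits and 1.54% of replicate 2 Z summits (odds ratio 8.18, Fisher's exact test, p = 1.03e-12). The window was picked for its number of shared summits, which needs replicate 1 summits. It is also the densest Z window of replicate 2 taken alone, a choice that works against this direction. The summits there are clustered and 21 are shared, so they are not the independent counts that the test takes them for. Random placement that is even along each chromosome is argued against by the highest window of the shuffles, 17. These shuffles kept no local density, so they cannot address uneven density or mappability. A feature of replicate 1 alone is argued against by the place of the window. Chosen from replicate 1 only, it was number 1 of 165 Z windows in replicate 2 (29 summits, the next 25), and number 11 among the windows of all chromosomes. A hypothesis is that the group covers the male hypermethylated (MHM) locus, a tandem repeat of the chicken Z known to be open and transcribed in females; without an annotation of the lists' build its identity was not tested (gaps between the summits ran from 0.48 to 62.0 kb), and neither was collapse of repeat copies in the assembly.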
